A study of Arabidopsis thaliana with 4 samples.

How the data were processed

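Chromatin was prepared from immature seeds of Arabidopsis thaliana, accession Col-0, collected 11 to 13 days after pollination, and cross-linked with 1% formaldehyde for 20 min, per the labels' protocols. Chromatin was sheared to about 500 bp, and 10 µg was incubated with 2 µg of a rabbit antibody raised against amino acids 2 to 237 of ABI3. ABI3 (ABSCISIC ACID INSENSITIVE 3) is a B3-domain transcription factor of seed maturation. Non-precipitated chromatin served as input. Per the labels, ChIP DNA was labelled with Cy3 and input DNA with Cy5, after ligation of adapters and amplification. Both were hybridised together on a pair of Agilent tiling array designs, so that 4 arrays cover 2 biological replicates. The Cy3 and Cy5 dyes were not swapped on any array. A dye effect of a probe therefore cannot be separated from ChIP enrichment of that probe, and counts of regions with ChIP below input under the same rule are given beside the counts of higher regions where they bear on them. No mock or non-immune precipitation was analysed here, so that unspecific precipitation cannot be separated from binding by ABI3 either.

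Per the file headers, the deposited scanner files came from Agilent Feature Extraction (version 10.5.1.1 per the submitters' processing notes), on probes designed for the genome build ath1:Jan2004. Per the file headers, the processed signal intensity of each channel was background-subtracted, detrended and scaled by 1 linear dye factor. The deposited log10 ratio is red over green, that is, input over ChIP, and was used only to check the direction; its correlation with log2(Cy3 / Cy5) was between -0.996 and -1.00. The authors' deposited value tables hold log2 ratios of ChIP over input whose normalization is not given in the sources used here. Across probes of each array they correlated with log2(Cy3 / Cy5) of the processed signals at 0.9995 or more, with slopes from 0.972 to 1.03 and medians from 0.01 to 0.04, and they hold no probes of the organelle genomes on the second design. Their scale and direction follow from this comparison, whereas the origin of the slopes stays unknown.

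The main values were log2(ChIP / input) of the processed signals, centred on the median of each array. No loess or quantile normalization was applied, since many probes may carry signal. Control spots and spots flagged as outliers (87 to 358 per array) were left out, and saturated spots were kept. Probe values of the 2 replicates were tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all 474585 probes. A probe was called higher at an adjusted p under 0.05 and a mean log2 ratio of at least 1, and lower at -1 or below. For regions, window means over probes within 500 bp of each probe, with at least 3 probes, were tested in the same way. A window was called at an adjusted p under 0.05, a mean of at least 1 and at least 1.5-fold in each replicate, and called windows within 500 bp formed 1 region. limma estimated an infinite prior degrees of freedom, so that every probe was tested against a common spread, a standard error of 0.23 for probes and 0.16 for windows on the log2 scale. A probe or window whose replicates disagree is thus not penalised for it, and the values of each replicate are given for the regions named. With 2 replicates, the number of arrays limits the precision.

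The calls were tested on simulated log ratios at the real probe positions. Of 100 probes raised 4-fold 100 were called, and of 100 raised 2-fold, exactly at the threshold, 52 were called, with 5 false calls among 472710 nuclear probes. Of 100 simulated peaks of 4-fold at the summit, 99 were called, with 0 false regions among 464491 windows. These peaks reached well past 500 bp on either side of the summit and were the same in both replicates. Narrower peaks were not simulated, so this recovery does not extend to them. In the simulation of single probes 1 probe was falsely called lower, whereas 625 nuclear probes were called lower on the arrays. The simulation thus does not reproduce all that the arrays hold, and its false calls are not a rate of false calls for them.

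RY core (CATGCA), full RY (CATGCATG), G-box (CACGTG) and ABRE core (ACGTG) were searched on both strands of the probe sequences, beside 3 control sequences with the composition of full RY. With no genome sequence of this build, the planned search of 250 bp around each peak was replaced by its planned substitute, probe sequences of called probes against 5 uncalled probes each, matched on length and GC. The planned matching on distance to the nearest transcription start needs gene positions and was left out. Called and matched probes may therefore differ in position relative to genes, which can bear on the odds ratios. The test was Fisher's exact test, two-sided, in scipy 1.17.1 under Python 3.11.15, with Benjamini-Hochberg adjustment over the 7 sequences and, for the ranks, over all 2080 distinct 6-mers. Neighbouring probes are not independent, which these p-values do not take into account. Differences over all nuclear probes were taken within strata of probe length and GC, with 95% intervals from 1000 bootstrap draws of 500 kb blocks.

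Genes are not named. The files give probe coordinates on ath1:Jan2004 and no gene names, and the gene table at hand names another assembly (TAIR10.1), between which coordinates were not converted. The 3 planned results that need gene positions (promoters, the 13 gene lists and the location of regions relative to genes) were therefore not run, and the rule for naming genes was replaced by naming the 10 regions with the highest peak. Any other region or 6-mer singled out was chosen after its values were seen. The tests, thresholds and alternatives were fixed before the data were examined, except where stated. Alternatives were normexp background correction (offset 50), within-array loess, correction for probe GC, probes well above background in the input only, the authors' values, saturated spots left out, other thresholds, windows and merging distances, other motif controls, and leaving out each replicate. No column of per-sample values was left unmatched to a sample.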

Results

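Immunoprecipitated and input chromatin of immature Col-0 seeds was compared on 4 tiling arrays, 2 biological replicates on each of the 2 designs, to locate DNA precipitated with the antibody against ABI3. With no mock precipitation analysed here, a region above input may hold unspecific precipitation as well as ABI3. The designs held 237695 and 237694 probes, spaced by a median of 171 bp on the nuclear chromosomes. At least 99.7% of probes were well above background in each channel of every array. Median signals in the 2 channels lay 28.0 to 54.8 times above those of negative control spots. Coordinates below are those of the genome build ath1:Jan2004, and genes were not assigned to them.

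ChIP signal was above input in 52 regions of the nuclear chromosomes. Of these, 12 were no longer called once probes had to be well above background in the input, and 40 were. The 40 regions had a median peak of 1.24 on the log2 scale, or 2.36-fold, and both replicates reached at least 1 at the peak in 31 of them. Their median length was 596 bp, from 46 to 4040 bp. Chromosomes 1, 2, 3, 4 and 5 held 12, 4, 6, 10 and 8 of them. Replicate 1 was higher than replicate 2 at the peak in 34 of the 40, by a median of 0.22 over all 40. Across probes, the log2 ratio correlated with probe GC at 0.29 and 0.23 on the arrays of replicate 1. On those of replicate 2 the correlation was -0.10 and -0.12. Whether this trend bears on the difference at the peaks was not tested. The same rule with the sign turned gave 44 regions below input, 10 of them on nuclear chromosomes, so that higher and lower nuclear regions numbered 52 and 10. Among probes well above background in the input they numbered 40 and 10. With normexp background correction they were 80 and 39, and with a 1.5-fold minimum in place of 2-fold 197 higher and 326 lower. The excess also shrank at the 2-fold minimum with windows of 250 bp either side and at least 2 probes in place of 3 (115 to 92). It shrank too when only replicate 2 was used (55 to 49), and with only replicate 1 it was 120 to 43.

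The strongest signal formed a block on chromosome 4. The region with the highest peak, from 13609895 to 13613934, reached 2.08 ± 0.04 (SD, n = 2; limma adjusted p = 1.77e-36), a 4.22-fold excess of ChIP over input, with 2.10 and 2.05 in the replicates. The neighbouring region from 13607200 to 13609367 reached 1.65 ± 0.34 (SD, n = 2), with 1.42 and 1.89 in the replicates. Together they spanned 6735 bp. Within this span the ratio rose and fell several times: in replicates 1 and 2 it was 1.80 and 1.55 at position 13607356, 0.76 and 0.90 at 13608748, 2.39 and 2.15 at 13609922, 0.14 and 0.79 at 13611120, and 2.34 and 2.41 at 13612095. These positions are the main extremes of replicate 1, and smaller turns, such as a fall and rise near the end of the span, are left out. The rises and falls listed appeared in both replicates. Of the 5 matching extremes of replicate 2, 3 lay at the next probe: 1.86 at 13607516, 0.77 at 13608574 and 2.39 at 13609337.

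**Figure D1:**
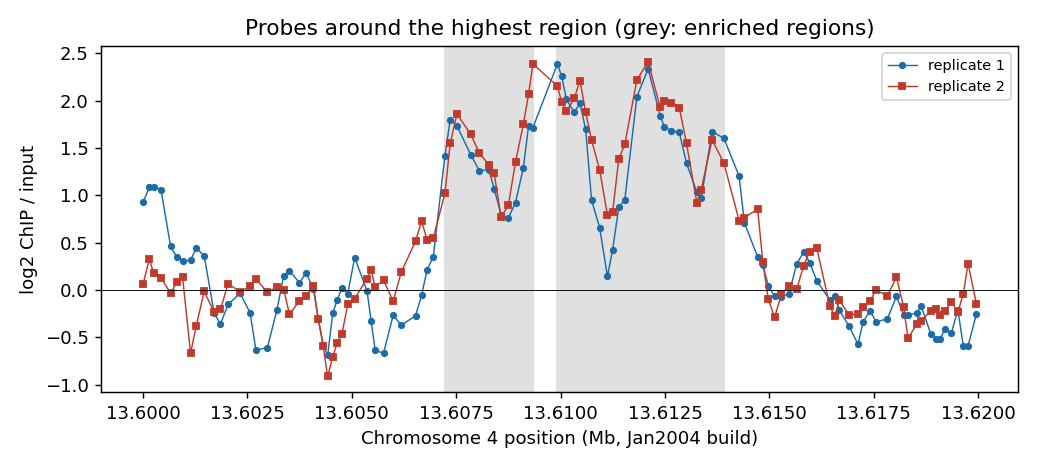
Log2 ratio of ChIP over input for each probe (vertical axis) against its position on chromosome 4 in Mb (horizontal axis), with replicate 1 as circles, replicate 2 as squares and the enriched regions in grey. Both replicates rise above 2 near 13609922 and 13612095 and fall between them, to 0.14 in replicate 1 and 0.79 in replicate 2.

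Chromosome 4 held another pair of the strongest regions. The region from 12900259 to 12901617 peaked at 1.79 ± 0.15 (1.90 and 1.69 in replicates 1 and 2), and that from 14087282 to 14089778 at 1.63 ± 0.03 (1.65 and 1.61), with SD over n = 2 in each. On chromosome 1, the region from 9647771 to 9649027 peaked at 1.89 ± 0.40 (2.18 and 1.60) and that from 2927893 to 2929098 at 1.66 ± 0.33 (1.89 and 1.43). The region from 5121560 to 5122893 on chromosome 3 peaked at 1.62 ± 0.42 (1.92 and 1.32), and the region from 122166 to 122793 on chromosome 5 at 1.59 ± 0.12 (1.67 and 1.51). In all of these regions, both replicates were above 1.3 at the peak, and all probes of the peak windows were well above background in both channels.

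The other 2 of the 10 highest regions lay in sequence that gave almost no signal in either channel. The region from 11232208 to 11234273 on chromosome 5 had log2 ratios of 2.52 and 0.69 in replicates 1 and 2, and the region from 12849398 to 12850000 on the same chromosome had 2.34 and 1.00. No probe of either peak window was well above background in ChIP or in input, so no fold is given for them. The former belongs to a stretch of 16740 bp, from 11226873 to 11243612, that contains 6 of the 52 regions. In this stretch 71 of 76 probes were not well above background in the input in both replicates, and 67 were not in ChIP. Median processed input there was 0.00133 times that of nuclear probes, a figure that rests largely on the surrogate values described next and is not a measured fold. The file flags a surrogate value, set by Feature Extraction in place of a measured signal, in both channels of 41 of the 76 probes in replicate 1 and of 46 in replicate 2. Those probes had nearly constant ratios, with medians of 1.60 (SD over probes 0.02) and 0.68 (SD 0.03), which are not measured ratios.

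**Figure D2:**
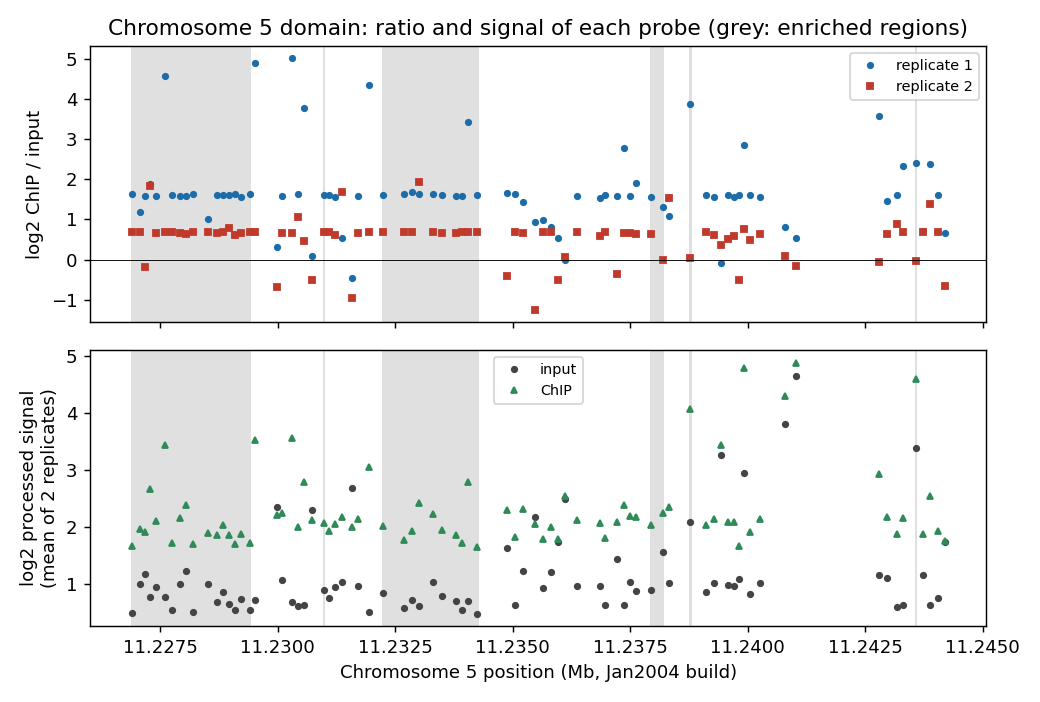
Each probe of the chromosome 5 stretch, with position in Mb on the horizontal axis. The upper panel gives log2 ChIP over input in replicate 1 (circles) and replicate 2 (squares), most of them near 1.60 and 0.68 where surrogate values were used, and the lower panel gives the mean log2 processed signal of input (circles) and ChIP (triangles); enriched regions are grey.

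**Figure D3:**
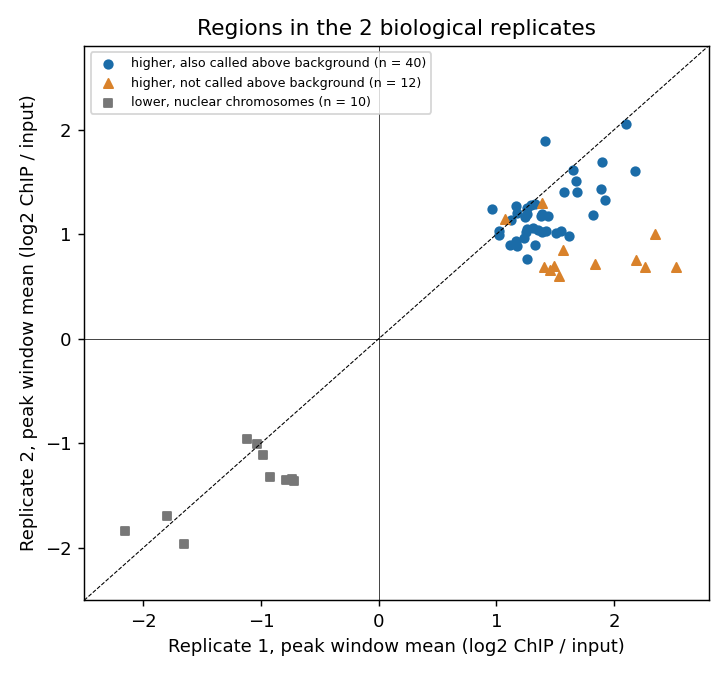
Peak window mean of each region as log2 ChIP over input in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with the line of equality dashed. The 40 regions also called among probes above background are circles, the 12 others are triangles and mostly have a higher ratio in replicate 1, and the 10 nuclear regions below input are squares.

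At the level of single probes, 713 of 474585 were called higher and 2496 lower, of which 712 and 625 were nuclear. Without adjustment, 20265 probes were higher and 30582 lower at p under 0.05. Of the 713 probes called higher, 252 (35.3%) were not well above background in the input of at least 1 replicate. This left 461 that were well above it in both, beside 607 nuclear probes lower. With a 1.5-fold minimum, 1782 probes were higher and 3555 nuclear probes lower. With replicate 2 alone and the fold threshold only, they numbered 1339 and 2523, and with replicate 1 alone 2221 and 2109; 394 and 622 of the 713 were among the 1339 and the 2221. The split of higher to lower calls moved with the scaling: it was 668 to 1099 with loess, 915 to 4630 with normexp, which kept 344 of the 713, and 683 to 617 with the authors' values, which lack the organelle probes. Nuclear probes called lower numbered 676, 2764 and 617 in these, so that most of the shift with loess and the authors' values lay in the organelle probes. The correlation of the replicates across nuclear probes was 0.21, and across nuclear windows 0.26. Probes and overlapping windows are not independent replicates. Both directions had more windows shared by the replicates than chance gives. In all, 163 nuclear windows had at least 2-fold more ChIP than input in both replicates, against 0.221 if the replicates were independent. At least 2-fold less was found in both for 20 windows. At 1.5-fold the shared windows were 781 higher and 676 lower, and at 2.83-fold 22 higher and 17 lower.

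Probes of the organelle genomes were far below input. Chloroplast probes had a median log2 ratio of -2.36 ± 0.16 (SD, n = 2), and 721 of 723 were called lower. Mitochondrial probes had -1.99 ± 0.30 (SD, n = 2), and 1150 of 1152 were called lower. Their input signals were 21 and 15.6 times the nuclear median. Of the chloroplast probes, 204 were saturated in at least 1 channel on both replicates, so that their measured depletion is a lower bound.

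The RY core is an element bound by B3-domain factors of the ABI3 type. It occurred in 21 of 712 called nuclear probes (2.95%) and in 51 of 3555 matched probes (1.43%), an odds ratio of 2.09 (95% interval 1.19 to 3.56; Fisher's exact test, p = 0.00966, adjusted over the 7 sequences 0.0225). Restricted to called probes above background in the input, the odds ratio was 2.40 (Fisher's exact test, p = 0.00653). When probes were called on 1 replicate by the fold threshold alone, it was 1.36 for replicate 1 and 1.35 for replicate 2 (Fisher's exact tests, adjusted p = 0.117 and 0.577). With the probe GC correction it was 1.91 (Fisher's exact test, adjusted p = 0.061). Of the 40 regions, 11 held a probe with the RY core between their ends, against a median of 3 (95% range 0 to 7) in 10000 random sets of runs of as many probes (permutation p = 0.0008, adjusted over 3 motifs 0.0012), a test added after the data were seen. Among all 2080 6-mers ranked by the test on called probes, the RY core was number 33 and did not pass adjustment (adjusted p = 0.593).

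The ACGT-containing elements bound by bZIP factors were also more frequent in called probes. The ABRE core was in 44 of 712 called probes (6.18%) against 2.95% of matched probes, an odds ratio of 2.16 (95% interval 1.47 to 3.14, Fisher's exact test, p = 7.2e-05, adjusted 0.000504). Of the 40 regions, 15 held a probe with it, against a random median of 5 (permutation p = 0.0004, adjusted over 3 motifs 0.0012). Inside the 52 regions its odds ratio of 1.91 did not pass adjustment (Fisher's exact test, adjusted p = 0.127). The G-box was in 10 called probes (1.40%) against 17 matched probes (0.478%), an odds ratio of 2.97 (Fisher's exact test, p = 0.00877, adjusted 0.0225), which became 3.35 with the probe GC correction (Fisher's exact test, adjusted p = 0.0637) and 1.67 without replicate 1 (Fisher's exact test, adjusted p = 0.635). CACGTG contains ACGTG, so probes with the G-box are also among those with the ABRE core. Only 2 of the 40 regions held a probe with a G-box (random median 0, random placement test, p = 0.234), and inside the 52 regions its odds ratio was 1.67 (Fisher's exact test, p = 0.627). Sequence between probes was not searched, so a region without such a probe may still hold the element. Over all nuclear probes both elements went the other way: ratios of probes with the G-box were lower by -0.08 and -0.06 on the log2 scale in replicates 1 and 2, and those with the ABRE core, set against probes over 3000 bp away, by -0.04 and -0.03, with 95% intervals below 0. Neighbours at 100 to 300 bp that lack the element were lower in replicate 2 only, by -0.045 for the G-box and -0.021 for the ABRE core. In replicate 1 their differences were 0.008 and 0.004, with intervals that included 0. The full RY sequence was in 2 called and 1 matched probes (Fisher's exact test, p = 0.0742), and the 3 control sequences were in at most 1 called probe each. Among 6-mers, 5 passed adjustment in called probes. With probes above background only, a ranking added after the data were seen, 1 passed, ACACGT (odds ratio 5.44, Fisher's exact test, adjusted p = 0.000648). On the other strand it reads ACGTGT, which contains the ABRE core, so it is not a result separate from that element.

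Over all nuclear probes, those with the RY core had slightly higher ratios than probes of the same length and GC. The difference was 0.04 on the log2 scale in each replicate, with 95% intervals of 0.030 to 0.047 and 0.028 to 0.044. Probes 100 to 300 bp from an RY core that lacked it themselves were higher than distant probes by 0.04 and 0.03. At 1000 to 1500 bp the difference was within its interval of 0 in both replicates.

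**Figure D4:**
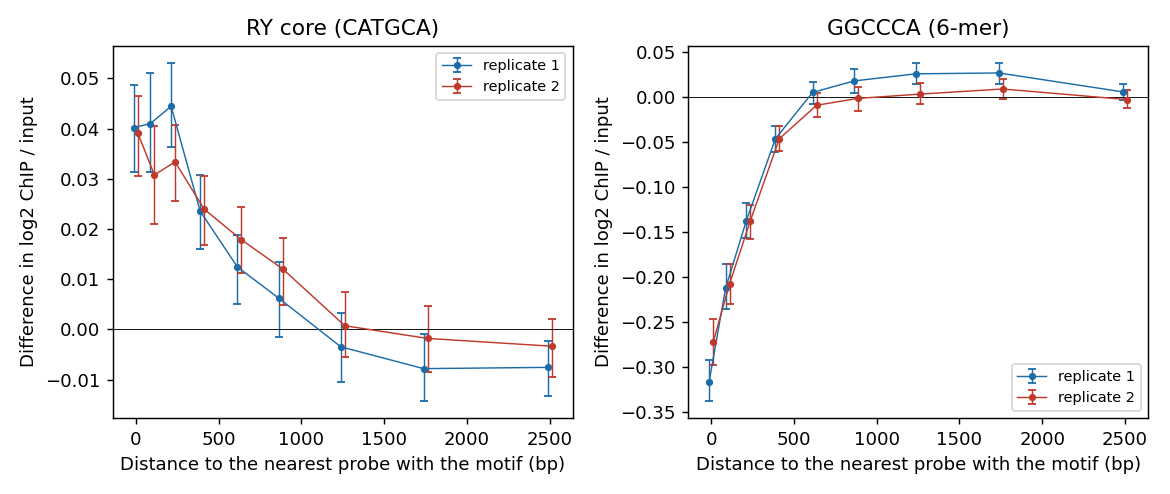
Difference in log2 ChIP over input (vertical axes) between probes at a given distance in bp from the nearest probe with a motif (horizontal axes) and probes over 3000 bp away, for the RY core and the 6-mer GGCCCA, by replicate, with 95% bootstrap intervals as bars. Probes near the RY core are higher by about 0.04, and probes with GGCCCA are lower by -0.32 and -0.27, in both cases fading with distance.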

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

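The alternatives without the chromosome 5 stretch and with probes inside regions were added after seeing the data. Signal over background limited the calls: with probes above background in the input only, 461 probes and 40 regions were called, all of the 461 among the original 713. Of the 713, normexp kept 344, replicate 2 alone 394, replicate 1 alone 622, loess 566, the GC correction 662 and the authors' values 664. The number of probes higher was 1782 with a 1.5-fold minimum and with the adjusted p alone, and 1339 to 2221 when a replicate was left out and the fold threshold alone was used. Regions higher and, on nuclear chromosomes, lower numbered 197 and 326 with the 1.5-fold minimum and 668 and 1410 with the adjusted p alone. They numbered 115 and 92 with 250 bp windows of at least 2 probes, and 80 and 39 with normexp. They were 120 and 43 without replicate 2 and 55 and 49 without replicate 1, and these held 51 and 37 of the 52 regions. Other settings gave 48 to 52 higher and 9 to 11 lower, and leaving out the chromosome 5 stretch 46 higher. The RY core's odds ratio was above 1 under every alternative run, from 1.35 to 5.24. By Fisher's exact p adjusted over 7 sequences it no longer passed 0.05 with the probe GC correction (1.91, adjusted p = 0.061), with controls matched on neither length nor GC and drawn with another seed (1.80, adjusted p = 0.0754), and without replicate 1 or 2 (1.35 and 1.36, adjusted p = 0.577 and 0.117). The G-box did not pass with the probe GC correction (3.35, exact adjusted p = 0.0637), without replicate 1 (1.67, exact adjusted p = 0.635; without replicate 2 it was 2.52 and passed), or inside the 52 regions and those called above background (1.67 in each, exact adjusted p = 0.878). Where called probes shifted, the cause was not tested, except that looser thresholds call more by construction and fewer arrays leave no test. For the 10 highest regions, 45 of 58 peak values under other settings moved by less than the replicates' SD, 13 moved further and 0 changed sign. With normexp the near-background regions at 12849398 and 11232208 on chromosome 5 fell from 1.67 and 1.60 to 0.39 each, the latter within its SD of 1.30. The 58 exclude the 20 values with a replicate left out, which are the values of the other replicate. No paired analysis was possible because there is 1 group and the ratio already pairs ChIP and input. Slide and replicate coincide, so no slide block could be fitted. Not run, for want of gene positions or a genome of this build: promoters, gene lists, locations, and the motif search in 250 bp around each peak with its 100 bp alternative.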

Other observations

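Stated before their values were seen were the tests of base composition, neighbours and rank for the RY core, of input signal in regions below input, and of GC and repeats in the chromosome 5 stretch. The intervals used below for base composition, rank and input signal in regions below input were not part of the stated rules. The rest of this part was chosen after results were seen. The 6-mers with the lowest ratios over all nuclear probes were GGCCCA and AGGCCC. The 1616 probes with GGCCCA were lower than probes of the same length and GC by -0.32 and -0.27 on the log2 scale in replicates 1 and 2, larger in size than the 0.05 of the highest 6-mer, GCTGCA. Probes 100 to 300 bp from GGCCCA that lack it were lower by -0.16 in each replicate, and the intervals of the difference included 0 at 500 to 750 bp. Farther away replicate 1 was higher, by 0.03 with an interval above 0 at 1500 to 2000 bp, while replicate 2 was not. The differences of all 2080 6-mers correlated between replicates at 0.845. After GCTGCA, the highest 6-mers by the mean of the replicates were GCATGC and ATGCAT. ATGCAT lies within the full RY sequence CATGCATG, whereas GCATGC overlaps it only in part. The next ones, CTGCAG, ATGCAG and ACAGGG, do not lie within it. Called probes and matched probes had an open reading frame through the whole probe in 80.9% and 81.9% of cases, a difference that was not detectable (Fisher's exact test, p = 0.559).

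The higher ratios of probes with the RY core were weighed against a base composition effect, a hybridisation effect of the motif and ABI3 binding at RY elements. A dye or hybridisation effect confined to the probe does not by itself account for the pattern. Neighbours at 100 to 300 bp that lack the motif were higher by at least 0.0322 with intervals above 0. Part of the difference at probes with the motif may still be such an effect, which the neighbours cannot exclude. Of 179 other 6-mers with the same bases, at most 3.91% had as large a difference in a replicate. This was under the share that had been stated as the mark of base composition. Up to 12.3% exceeded the lower end of the RY core's interval. That comparison was not part of the stated rule, and because of it base composition is left open. The RY core ranked 58 and 42 of 2080, outside the top 20 that had been stated as the mark of binding. The stated mark was thus missed in both replicates. The RY core's intervals, up to 0.047 and 0.044, include the value of the 6-mer at rank 20 (0.046 and 0.041), a comparison also outside the stated rule. This rank therefore does not tell binding at RY elements apart from a wider preference for such sequence.

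In nuclear regions below input, 3 longer regions may reflect sequence shared with the organelle genomes. They lie on chromosome 3 from 13542444 to 13544440 (-1.997 at the peak) and on chromosome 2 from 3313237 to 3315059 (-1.81) and from 3188172 to 3188804 (-1.75). Their median input signal was at the 99.99th percentile of nuclear probes, 8.76 times the median, and 5 of their 19 probes shared a run of 16 bases with an organelle probe, against 1.36% of nuclear probes sampled. The other 7 regions, of 1 or 2 windows, had a median input at the 31.4th percentile (95% interval 1.21 to 64.0) over 9 probes. A value below the nuclear median had been stated as the mark against shared sequence, but 9 probes are too few to place it there. Of these 7 regions, the one on chromosome 2 from 3565400 to 3565450 had an input of 13.7 on the log2 scale, above the 95th percentile of nuclear probes (11.74), from 1 probe. No biological explanation was tested for them.

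The chromosome 5 stretch, enriched mainly in replicate 1, may be a product of signal near background: 93.4% of its probes were not well above background in the input in both replicates. Its ratios are largely those of surrogate values, in both channels of 41 and 46 of 76 probes in replicates 1 and 2. The 313 other nuclear probes not well above background had median ratios of 1.35 and 0.61, against 1.60 and 0.67 over the stretch. The difference between replicates was 1.18 after GC correction (95% interval 0.94 to 1.43), but it is largely one between surrogate values, so this says nothing on a trend of replicate 1 with probe GC. The median input signal of the stretch was not raised, at percentile 0.0271 of nuclear probes. Repeated sequence cannot be judged from it, since most of these probes gave no measured signal. Whether this stretch is absent from the seeds' genome or fails to hybridise was not tested.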
